A study of Homo sapiens with 2 samples.

How the data were processed

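Gene expression was measured on Illumina expression arrays in 2 samples of total RNA from MCF-7, an estrogen receptor-positive human breast cancer cell line. Per the labels, the vector sample came from cells carrying the empty expression vector pQCXIP and the G1P3 sample from cells carrying pQCXIP-G1P3, where G1P3 is the older name of the interferon-induced gene IFI6. The groups were taken from these labels, which gave 1 array per group. RNA had been treated with DNase, checked on a Bioanalyzer and labelled with biotin, per the labels' protocols.

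The deposited values were probe intensities on a linear scale for 47322 probes. GenomeStudio version 2011.1 was named in the submitters' processing notes without its role. The other upstream steps, the detection calls and a genome build were not given in the sources used here. From the values themselves, 27.3% of probes on each array lay below 0, as background subtraction leaves them. The sorted values of both columns differed by at most 1.1 signal units at any position, as quantile normalization between arrays leaves them. Such a normalization gives both arrays the same distribution, so a shift shared by most transcripts cannot be seen in these values.

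Probes were named through the platform's probe annotation, which listed 30121 of the probes with a gene. Of these, 30113 had 1 gene symbol and 8 had several, and the remaining 17201 probes were unnamed here. Gene numbers of 30074 named probes were found in a table of current human genes, and 39 named probes kept the annotation's symbol. No coordinates are given, and the order of genes along chromosomes, used for the runs of neighbouring genes, came from that table, which uses the human assembly GRCh38.p14.

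Differences were computed as log2(signal + 16) in the G1P3 array minus the same in the vector array, with no further normalization. Fold values taken from this scale understate differences of dim genes. Genes were analysed in the brighter part of the arrays, defined as probes whose higher array reached the 60th percentile of all probes, a signal of 7.2. This left 21114 probes and 11819 genes, with each gene represented by its probe of highest mean log2 signal. A further 5409 probes of the brighter part had no single listed gene and entered no gene count. A probe that reached the 60th percentile on 1 array only was higher on that array by the rule itself. With 1 array per group there was no replicate error, so no p-value, standard error or test between the groups is given, and genes were counted by fixed sizes of 2-fold and 1.5-fold. The number of arrays limits the precision of every value. The only repeat measurement was technical: the spread and the direction of different probes of the same gene on the same RNA, with exact Clopper-Pearson 95% intervals for shares of genes.

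A background limit of 15.3 signal units, the size of the lowest deposited value, was set after the values had been seen. On each array 30.0% of probes lay above it. Where a gene lay below it on 1 array, the fold is given as a lower bound, the brighter signal over the limit. Where it lay below the limit on both arrays, no fold is given. Counts by size use the log2 scale for every gene of the brighter part, those below the limit included. The sizes themselves were meant to be counted, but a gene exactly at 1.5-fold, such as COL5A2, could be left out by rounding.

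The comparisons, the lists of genes, the rule for named genes and 10 of the 11 alternative settings were fixed before the data were examined. Named genes were every IFI6 probe, the 15 genes with the largest positive and the 15 with the largest negative log2 difference whose symbols were not provisional names, and up to 4 members per list with the largest absolute difference. Any other gene named was chosen after its values were seen. The 28 gene lists held 1071 symbols, of which 1051 were matched to 987 different genes. For each list with at least 5 members in the brighter part, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean log2 signal. This percentile describes these 2 arrays and is not a test of the groups. Of the lists, 27 had a percentile, and 1.35 of them would lie outside the central 95% if their genes varied independently, as genes of random lists do.

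The alternatives were quantile normalization, median centring, a lowess curve with a span of 0.3, an offset of 64, a floor at the median signal, brightness limits at the 40th and 75th percentiles, no brightness limit, the brightness limit on both arrays, the mean of a gene's probes, and the added floor at the background limit. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedure was tested on simulated data for the comparison of G1P3 against vector with 11787 genes, of which 200 were given known differences. It found 96 of 100 genes simulated at 3-fold and 100 of 100 at 6-fold past the 2-fold size. Of 11587 unchanged genes, 13 passed that size. Variation between cultures cannot be estimated from 1 array per group. These shares therefore describe the simulated data only and are not error rates for the genes counted in the real arrays. Of 100 simulated lists with no shift, 1 lay outside the central 95%, and a list of 30 genes shifted by 0.3 on the log2 scale reached percentile 100.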

Results

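The series compared the RNA of MCF-7 cells stably carrying G1P3 (IFI6) with that of MCF-7 cells stably carrying the empty vector, to find how G1P3 alters gene expression in an estrogen receptor-positive breast cancer line. The title of the series places the G1P3 protein in mitochondria and connects it with protection from apoptosis, with reactive oxygen species and with metastatic potential. Each group had 1 array, so none of the differences below has a replicate check, and any other difference between the vector and G1P3 cells is included in them. Both arrays had a median signal of 4.1, an upper quartile of 27.7 and a highest signal of 12470. The signals of the brighter probes correlated across the arrays with a Spearman coefficient of 0.950, computed across probes, which are not independent replicates.

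IFI6, the introduced gene, was higher in the G1P3 array on both of its probes, in the direction the labels give. Probe ILMN_2347798 had a signal of 35.7 in the vector array and 333.1 in the G1P3 array, a log2 difference of 2.76 or 6.75-fold, the largest positive difference among all probes of the brighter part. Probe ILMN_1687384 had signals of 224.3 and 343.1, a log2 difference of 0.58 or 1.49-fold, at the 95.8th percentile. The annotation assigns the probes to different IFI6 transcripts, NM_022872 and NM_022873. Their positions relative to the introduced sequence were not determined, so the smaller difference cannot be read as the level of the introduced transcript.

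Most genes had similar signals on both arrays (SD of the log2 differences from their median absolute deviation, 0.286). CCDC85A, DIO2, PPP2R2B and BCL2L1 had the largest positive differences, and SCIN, PLS3, TFF3 and TARP the largest negative ones. Of 11819 genes, 94 (0.795%) were at least 2-fold higher and 51 (0.432%) at least 2-fold lower in the G1P3 array. Past 1.5-fold, 447 were higher and 379 lower. Among the 9393 genes whose brighter signal exceeded the background limit, 79 were higher and 38 lower at 2-fold. The 2-fold counts depended on the treatment of dim signals, with 28 higher and 13 lower for an offset of 64 and 593 higher and 567 lower for a floor at the median signal.

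**Figure D1:**
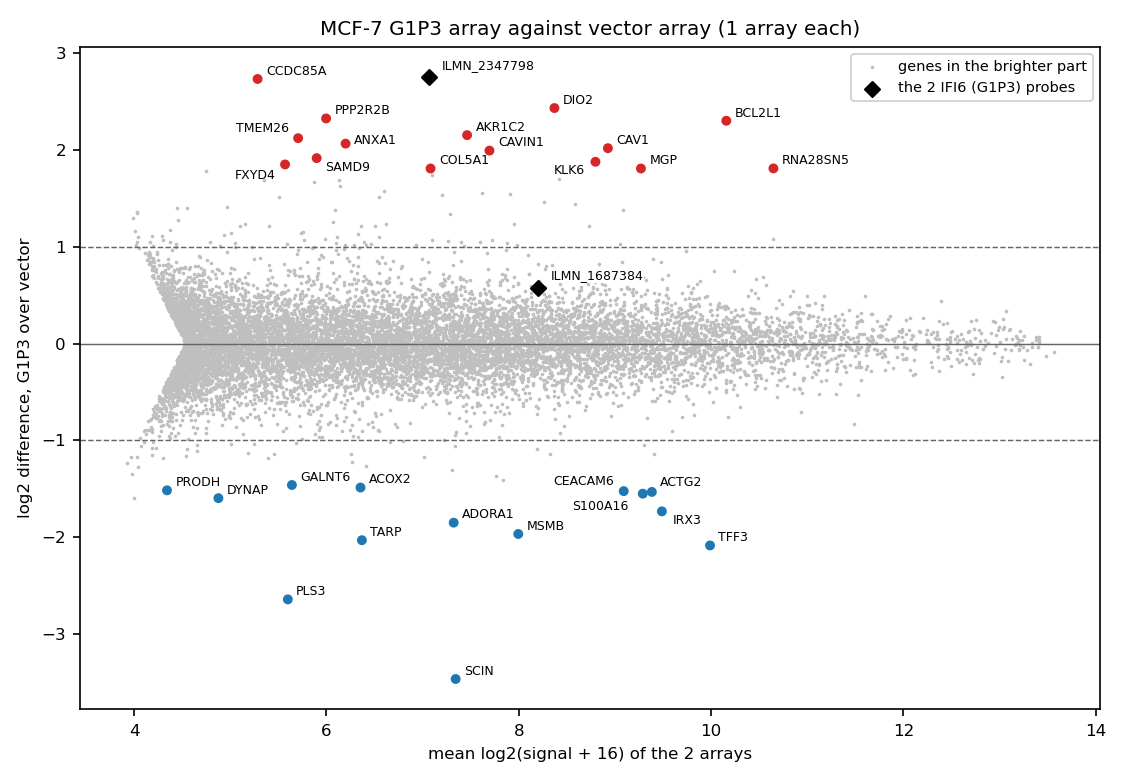
Log2 difference (G1P3 over vector) against mean log2(signal + 16) for genes of the brighter part, 1 array per group; dashed lines mark 2-fold, red and blue points the named highest and lowest genes (HMCN1, below the background limit on both arrays, is grey), and black diamonds the 2 IFI6 probes. Differences of dim genes spread more widely than those of bright genes, and BCL2L1 and RNA28SN5 at the upper right and TFF3 at the lower right stand away from genes of similar brightness.

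BCL2L1, which encodes the antiapoptotic protein BCL-XL, had a signal of 498.3 in the vector array and 2524.1 in the G1P3 array, 4.94-fold higher, and its other probe differed by a similar log2 value, 2.32 against 2.30. CAV1, a structural protein of caveolae, had signals of 225.7 and 964.8 (4.06-fold), and CAVIN1, which coats these small pits of the plasma membrane, had 87.8 and 398 (3.99-fold). MGP, an inhibitor of matrix calcification, was 3.51-fold higher (313.9 and 1141.5) and the collagen chain gene COL5A1 also 3.51-fold higher (56.4 and 238). DIO2, a deiodinase that activates thyroid hormone, was 5.41-fold higher on its brightest probe (126.4 and 754.3), and its other probe had signals of 5.8, below background, and 24.4. AKR1C2, a steroid-metabolising aldo-keto reductase, was 4.46-fold higher on a probe that may also bind transcripts of its close paralogs. The other probes of AKR1C2 were all below background on both arrays. The phospholipid-binding gene ANXA1 was 4.19-fold higher (19.9 and 134.5, a ratio of 6.76 without the offset) and the secreted protease gene KLK6 3.68-fold higher. RNA28SN5, a ribosomal RNA of the large subunit, was 3.51-fold higher on its brighter probe, with a log2 difference of 1.07 on the other.

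For several of the higher genes the representative probe was not above background in the vector array. CCDC85A was at least 5.53-fold higher in the G1P3 array, but its other probe was below background on both arrays (3.9 and 7.1). TMEM26 was at least 6.08-fold higher, FXYD4, a regulator of sodium transport, at least 4.86-fold, and SAMD9, an interferon-inducible antiviral gene, at least 6.54-fold. PPP2R2B, a regulatory subunit of a protein phosphatase, was at least 8.31-fold higher on that probe, but another probe, assigned to a different transcript, was above background on both arrays with signals of 39.4 and 49.9, a log2 difference of 0.25. The gene's difference was 0.34 under both floors, where that other probe represented it.

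On the lower side, SCIN (scinderin), which severs actin filaments, had a signal of 523.9 in the vector array and 32.9 in the G1P3 array, a log2 difference of -3.46 and the largest of either direction among genes. PLS3 (plastin), which bundles them, was at least 6.87-fold lower, from 105.1 to below background, and its other probe had signals of 35.6 and, below background, 4.8. The smooth-muscle actin gene ACTG2, similar in sequence to other actins, was 2.89-fold lower. TFF3, a trefoil peptide of mucosal secretions, was 4.24-fold lower (2077.8 and 477.6), MSMB, a seminal plasma protein, 3.91-fold lower with all 3 of its probes lower, and the adhesion protein gene CEACAM6 2.87-fold lower. The adenosine receptor gene ADORA1 was 3.60-fold lower, the homeobox gene IRX3 3.32-fold, TARP, a transcript of the T-cell receptor gamma locus, 4.09-fold, the calcium-binding protein gene S100A16 2.93-fold and ACOX2, an oxidase of peroxisomes, 2.80-fold. In the G1P3 array GALNT6, which starts O-glycans on mucins, was below background and at least 4.37-fold lower, DYNAP at least 2.29-fold lower, and PRODH, which breaks down proline, lay near background on both arrays (18.3 and -4). HMCN1 was below the background limit on both arrays (11.7 and -6.8).

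**Figure D2:**
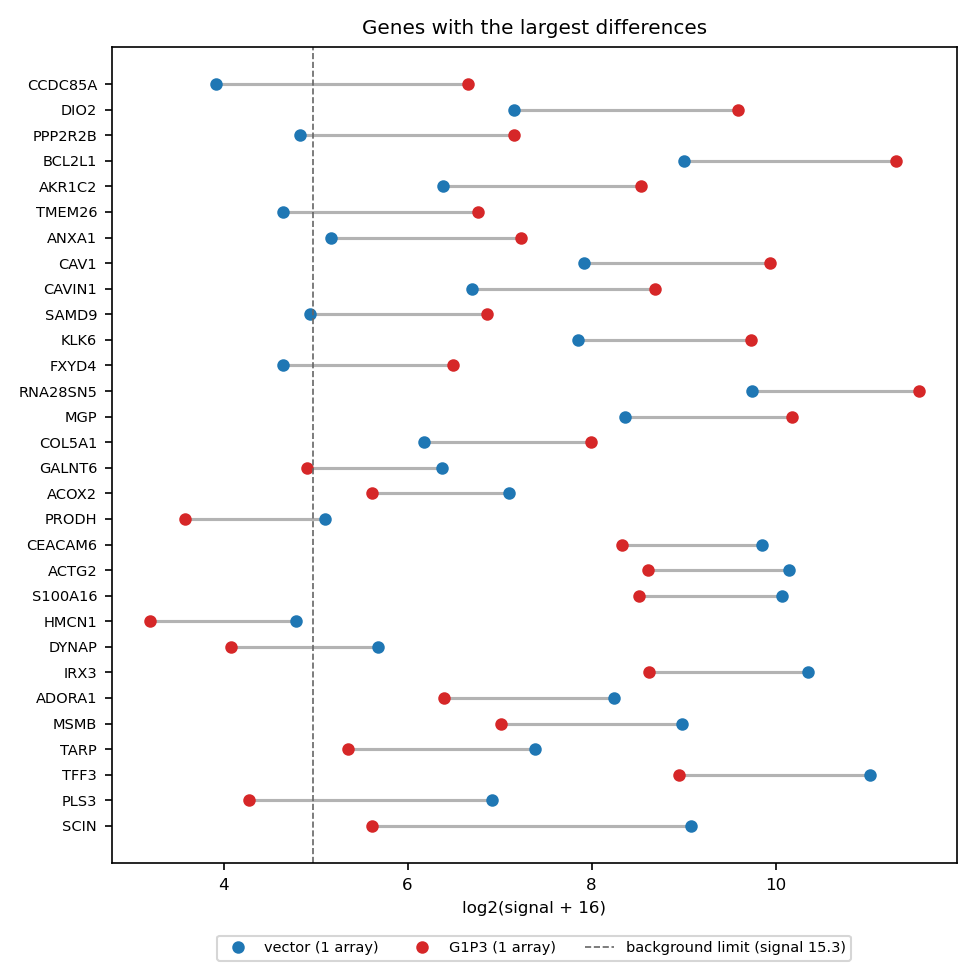
Signal of the 15 highest and 15 lowest named genes as log2(signal + 16), blue for the vector array and red for the G1P3 array, 1 array each, with the background limit of 15.3 signal units as a dashed line. BCL2L1, RNA28SN5 and MGP differ well above the background limit on both arrays, while CCDC85A, TMEM26 and FXYD4 in the vector array and PLS3, DYNAP and PRODH in the G1P3 array lie below it.

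Different probes of the same gene gave a measure of technical error. Over 2336 genes with 2 probes, the SD of a single probe's log2 difference was 0.224, from 0.184 in the brightest genes to 0.290 in the dimmest. It was estimated from the median absolute difference between the 2 probes of a gene. Probes of the same gene pointed in the same direction for 144 of 170 genes past 1.5-fold (84.7%, exact 95% interval 78.4 to 89.8) and for 39 of 40 genes past 2-fold (exact 95% interval 86.8 to 99.9). Over all 3035 genes with several probes the share was 55.8%. These repeats share the RNA and the array and so do not cover differences between samples of cells. Without the brightness limit the share past 1.5-fold was 52.7%.

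Basal and mesenchymal marker genes were higher and luminal epithelial markers slightly lower in the G1P3 array. Of 37 basal and mesenchymal markers 16 were in the brighter part, of which 7 were higher past 1.5-fold and none lower, with a median log2 difference of 0.50 at percentile 100 of the random lists (central 95%, -0.18 to 0.20). ANXA1 and CAV1 led, followed by CAV2, the partner of CAV1, at 168.4 and 492.6 (2.76-fold), with all 3 of its probes higher. The basal keratin gene KRT5 was below the background limit on both arrays (-4.6 and 7.6), as were 4 of the 16 genes in all, and VIM, the intermediate filament gene of mesenchymal cells, was lower, at 49.5 and 32. Without CAV1 and CAV2 the median was 0.43, and under the alternatives it ranged from 0.18 without the brightness limit to 1.03 with a floor at the median signal. The fibroblast markers, a list of another cell type, were higher alongside (6 of the 20 are also in other lists, 2 of them measured), with a median of 0.47 over 10 of 20 genes (percentile 99.97), 3 of them counted as higher past 1.5-fold (MGP, COL5A1 and COL6A3) and none as lower. Apart from MGP and COL5A1, COL6A3 (0.5 and 10.7) and COL5A2 (13.7 and 3.8) had the next largest differences. COL5A2 was exactly 1.5-fold lower and was left out of the count by rounding. Both were below the limit on both arrays, as were 5 of the 10 in all. COL6A3 reached the brightness limit only in the G1P3 array and COL5A2 only in the vector array, so that limit fixed their directions. The list's median ranged from 0.04 with a floor at the limit to 1.22 with a floor at the median signal. Markers of basal breast and HEK-type packaging cells, 9 of whose 18 members are also in other lists, had a median of 0.24 (10 genes, 3 higher, none lower, percentile 98.3) with CAV1, KRT5, LAMB3 (39 and 95.7) and VIM as the largest differences. The list lay inside the random range under 7 of the 11 alternatives, with medians from -0.02 (75th percentile) to 0.20 (40th percentile). Leukocyte markers had a median of -0.11 over 7 of 22 genes (percentile 23.2), of which LCP1, an actin-bundling plastin, was lower (411.9 and 184.6). CD14 differed by -0.51 on the log2 scale, CD53 (9.6 and 1.4) and CD79A (9.6 and 14.6) were below the background limit on both arrays, and the list's median was 0.03 without the brightness limit.

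The luminal epithelial markers had a median of -0.11 over 26 of 28 genes (percentile 1.14, central 95% -0.09 to 0.11), with 15 of them lower, 10 higher and 1 equal on both arrays. Past 1.5-fold, 3 were lower, TFF3, the epithelial transcription factor gene SPDEF (459.5 and 200.2) and the mucin gene MUC1 (1485.1 and 873.1), and 1 was higher, the progesterone receptor gene PGR (21.2 and 56.8). The estrogen receptor gene ESR1 differed by a log2 value of -0.26 and GATA3 by -0.09. Estrogen-induced genes had a median of 0.08 and a mean of 0.01 over 38 of 40 genes, inside the random range (percentile 94.0), with 4 higher and 3 lower past 1.5-fold. TFF3 and PDZK1 (log2 difference -0.73) were on the lower side of that list and PGR (0.97) and ELOVL2 (0.82) on the higher side.

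Matrix remodelling and migration genes did not stand apart as a group, with a median of 0.04 over 32 of 48 genes (percentile 77.3) and 3 higher and 1 lower past 1.5-fold. Within the list, the protease inhibitor gene SERPINE2 (31 and 85.1) and the laminin chain gene LAMB3 were higher, the metalloproteinase gene MMP16 was at least 1.18-fold lower (18 and, below background, 2) and PLAU, the urokinase gene, at least 1.62-fold higher (10.8, below background, and 24.8). Cytoskeleton and small GTPase genes had a median of -0.03 over 38 of 46 genes (percentile 16.8) with 1 higher, DIAPH2 (log2 difference 0.77), and 1 lower, RHOB (-0.65). TPM2 differed by -0.53 and CDC42 by 0.48. TGF-beta target genes had a median of 0.23 over 22 of 31 genes (percentile 99.9), with 5 higher and 4 lower past 1.5-fold, so the members differed in both directions. The list also holds receptor and ligand genes, so its median does not measure the response of target genes alone. The receptor gene TGFBR2 (22.8 and 109.8, 3.24-fold), the feedback gene PMEPA1 (355 and 741.2, with smaller log2 differences of 0.59 and 0.29 on its other probes) and the ligand gene BMP7 (595.6 and 1172.7) were higher and the ligand gene TGFB3 lower (log2 difference -0.83). The median lay inside the random range for a brightness limit at the 40th percentile (0.11) and without that limit (0.06).

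Among BCL2 family and apoptosis regulators, BCL2L1 was the only gene past 1.5-fold of 33 measured out of 40. The list's median was 0.17 (percentile 99.6), with 23 of the 33 higher, and 0.14 without BCL2L1. The inhibitor of apoptosis gene BIRC5 differed by 0.56, and the proapoptotic gene BID by 0.50 (-0.04 on its other probe), while BCL2L11, also proapoptotic, was below background in the vector array and at least 1.24-fold higher. The median was inside the random range for a brightness limit at the 75th percentile (0.08) or on both arrays (0.09), for the mean of a gene's probes (0.04) and for a floor at the background limit (0.01).

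Mitochondrial genes differed little. Nuclear-encoded oxidative phosphorylation genes had a median of -0.05 over 63 of 68 genes (percentile 1.89), with 39 lower and none past 1.5-fold in either direction. The largest differences were those of the ATP synthase subunit genes ATP5F1D (-0.50, but 0.11 on its other probe), ATP5F1C (-0.40) and ATP5F1E (-0.39) and of NDUFA8 of complex I (0.33). This list lay inside the random range under 4 alternatives, with medians of -0.05 to -0.03. Genes of mitochondrial biogenesis, dynamics and import had a median of -0.08 over 39 of 46 genes (percentile 2.38), with 1 lower, the uncoupling protein gene UCP2 (-0.66), and 1 higher, the mitophagy kinase gene PINK1 (0.62), past 1.5-fold. BNIP3L differed by 0.50 and CLPP by -0.46, and the list was inside the random range under 4 alternatives (-0.09 to -0.07). None of the 13 mitochondrial genome transcripts was measured. Antioxidant and NRF2 target genes, which respond to oxidative stress, had a median of -0.00 and a mean of 0.05 over 41 of 50 genes (percentile 41.6), with 3 higher and 2 lower past 1.5-fold. The 3 higher genes were the aldo-keto reductases AKR1C2 (on its brightest probe only), AKR1C3 (48.2 and 135.4) and AKR1B10 (7.1, below background, and 31.6). The metallothionein gene MT2A was lower (1044.6 and 550.2). Glycolysis and hypoxia response genes had a median of -0.05 and a mean of 0.05 over 34 of 40 genes (percentile 14.7), with the transcriptional repressor gene BHLHE40 higher (124.7 and 395.4) and the hexokinase gene HK2 lower (194.9 and 89.5, with 54.6 and 38 on its other probe, not past 1.5-fold). PFKFB3 differed by 0.53 (-0.11 on its other probe) and CA12 by 0.52, and for a brightness limit at the 75th percentile the list's median, -0.09, lay outside the random range.

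Interferon-stimulated genes other than IFI6 had a median of 0.18 over 28 of 46 genes (percentile 99.4, central 95% -0.14 to 0.14), with 5 higher and 2 lower past 1.5-fold. SAMD9 was the highest and PARP12 was also higher (12, below background, and 29.3, at least 1.92-fold), whereas the RNA sensor gene IFIH1 (-0.87) and PARP9 (-0.90, and -0.08 on its other probe) were lower. Both arrays were below the background limit for 9 of the 28, and the median lay inside the random range for a brightness limit at the 40th percentile (0.09) and without that limit (0.08). Antigen presentation and interferon-gamma response genes had a median of -0.07 over 15 of 31 genes (percentile 22.5), with 1 lower past 1.5-fold, B2M, the light chain of class I molecules (1155 and 685.8), whose other probe (403.6 and 346.3) did not pass it. B2M lies in a stretch of neighbouring genes with lower signals. HLA-DRA differed by -0.43, and ICAM1 and PSMB9 were below the background limit on both arrays. NF-kB and inflammatory genes had a median of -0.06 over 18 of 40 genes (percentile 22.6), 9 of them below the limit on both arrays, among these PTGS2, ICAM1 and RELB, while the subunit gene NFKB2 was at least 2.03-fold lower (31 and, below background, 11.9).

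Proliferation genes were close on the 2 arrays. The G2/M and mitosis list had a median of -0.01 over all 44 genes (percentile 35.1) with none past 1.5-fold, BIRC5 and UBE2C (-0.51, also in a stretch of lower neighbours) differing most, followed by MAD2L1 (-0.50, whereas its other probe had 4.8, below background, and 17) and CDC25B (-0.49). DNA replication and G1/S genes had a median of 0.10 over 43 of 47 genes (percentile 98.5), with 29 higher and only RRM2 (-0.60) past 1.5-fold. E2F2 differed by 0.51, MCM4 by 0.39 and UHRF1 by 0.36 (0.11 on its other probe), and the median lay inside the random range for the mean of a gene's probes (0.07) and an offset of 64 (0.08). Replication-dependent histone genes, whose messages usually but not always lack a poly(A) tail, had a median of 0.28 over 23 of 28 genes (percentile 100, central 95% -0.12 to 0.14). Of these, 21 were higher, 3 of them past 1.5-fold, and none was lower past it. H2AC18 had signals of 572 and 947.1, H2BC21 differed by 0.62 on the log2 scale, H2AC21 was below background in the vector array and at least 1.75-fold higher, H4C2 was near the background limit (5.1 and 15.4), and close paralogs may share these probes. Ribosomal RNA was higher in the same array, with RNA18SN5 at 173.3 and 600.8 (3.26-fold) beside RNA28SN5. Cytosolic ribosomal protein genes, the reference list, had a median of 0.04 over 67 of 76 genes (percentile 84.2), with 3 higher past 1.5-fold, RPL21 (1086 and 2313.7), RPL37 (0.69) and RPL10, which was below the limit on both arrays. RPL14 differed by 0.46, and for the mean of a gene's probes the list's median, 0.10, lay outside the random range.

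The remaining lists, among them those of stress responses, lay inside the random range. Unfolded protein and integrated stress response genes had a median of -0.04 over 33 of 41 genes (percentile 14.6) with none past 1.5-fold, and DNAJB9 (0.48), PSPH (-0.42, and 0.05 on its other probe), DDIT3 (-0.42) and the chaperone gene HSPA5 (0.37) differed most. Cholesterol biosynthesis and SREBP targets had a median of 0.02 and a mean of -0.01 over 27 of 33 genes (percentile 56.1), also with none past 1.5-fold, FADS1 differing by 0.49, HSD17B7 by -0.47, TM7SF2 by -0.45 and EBP by -0.41. p53 target genes had a median of 0.01 and a mean of -0.01 over 25 of 31 genes (percentile 54.7), where only PLK3, below the limit on both arrays, passed 1.5-fold. GADD45A differed by 0.57, PLK2 by -0.52 and the cell-cycle inhibitor gene CDKN1A by 0.49. AP-1 and immediate early genes had a median of 0.02 over 29 of 37 genes (percentile 62.1), with PHLDA1 higher (217 and 619.2, and 20 and 48.7 on another probe) and the transcription factor gene KLF2 (141.5 and 62.6) and SPRY4, the latter below the limit on both arrays, lower. DUSP4 differed by -0.44. Heat shock genes had a median of -0.04 over 22 of 26 genes (percentile 19.3), with HSPB8 (0.64) higher and HSPA6, below the limit on both arrays, lower past 1.5-fold, while BAG3 differed by -0.35 and CHORDC1 by -0.32. Housekeeping genes had a median of -0.06 over 20 of 24 genes (percentile 6.59), with B2M and PPIA (25.4 and, below background, 10.1) lower past 1.5-fold, TFRC at -0.51 and GUSB at 0.49.

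**Figure D3:**
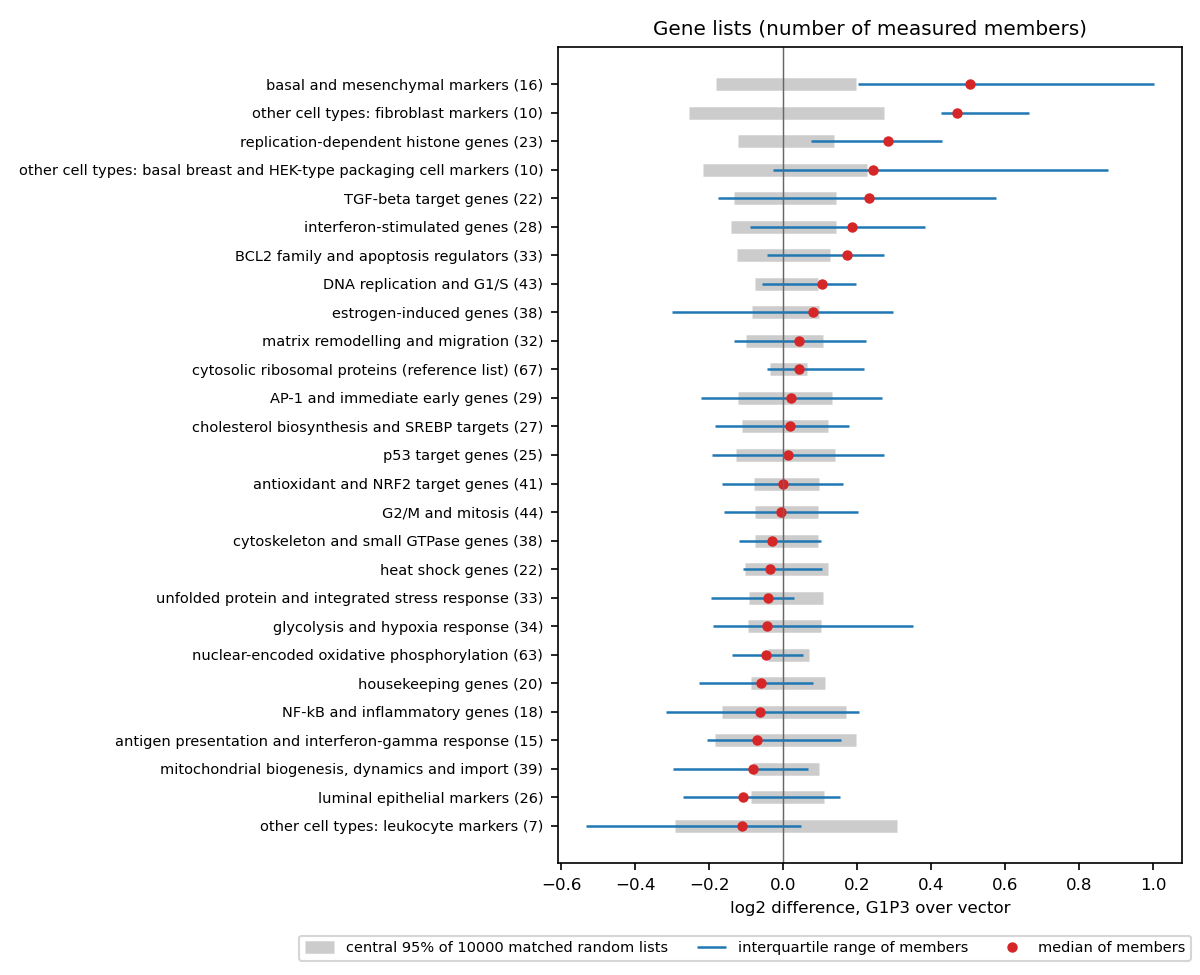
Median log2 difference (G1P3 over vector, red points) of each gene list with the interquartile range of its members (blue lines) and the central 95% of 10000 matched random lists (grey bars), 1 array per group; numbers in brackets are measured members. Medians of 8 lists lie above and 3 below the grey bars, with the basal and mesenchymal markers at 0.50 and the fibroblast markers at 0.47 farthest to the right.

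Over the 27 lists with a percentile, 8 lay above and 3 below the central 95% of random lists, and some lists share genes. For genes that vary independently, as in the random lists, 1.35 would lie outside. Genes of a list can vary together, so 1.35 is too low a reference and the excess cannot be read as evidence. The basal and mesenchymal, histone and luminal lists lay outside the central 95% under each alternative run, of which quantile normalization and median centring could move almost nothing in these already normalized values.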

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

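In this part the tests of gene order and of the S-phase list were chosen after the result was seen. Probes without a single listed gene belong to none of the comparisons above, and 43 of those in the brighter part were at least 2-fold higher in the G1P3 array and 34 at least 2-fold lower. There were 5409 such probes in the brighter part, against 94 higher and 51 lower of 11819 genes. The share of higher probes was thus close to that of the genes, and the share of lower probes somewhat larger. Probe ILMN_1801442 had a signal of 588.6 in the vector array and 87.1 in the G1P3 array, and probe ILMN_3280565 had 1853.1 and 406.6. Among the higher probes, ILMN_3275489 had signals of 273.2 and 1065.9, and ILMN_1800488 had -4.4 and 37.1. No explanation was tested for these probes.

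Neighbouring genes on chromosomes 15 and 20 were lower together in the G1P3 array. From ZNF106 to SLC27A2 on chromosome 15, 40 of 44 genes were lower with a median log2 difference of -0.40, and from ADA to CDH22 on chromosome 20, 25 of 26 were lower with a median of -0.39. The lowest median of 15 neighbouring genes was -0.47, below the lowest of 200 shuffled gene orders (-0.43), which argues against a chance order of genes, and 18 other probes of these genes, not used to find the stretches, had a median of -0.31 with 16 lower, which argues against noise of single probes. A candidate explanation that stays open is fewer copies of these segments in the G1P3 cells than in the vector cells, by a loss in the former or a gain in the latter. No DNA was measured, the labels do not give the number of cultures or clones, and an effect of G1P3 on these regions stays open as well.

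Caveolin, basal and fibroblast markers were higher in the G1P3 array. Fibroblast or mesenchymal cells mixed into the culture would bring their abundant transcripts, and the signal of VIM differed by -17.5, COL1A1 by -0.8, COL1A2 by -5.6, SPARC by 8.7 and LGALS1 by 144.8, with a median of -0.80. The planned bound on this median, relative to the 739.1 of CAV1, was not used, because it sets signals of different probes against each other and 3 of the 5 genes were below the background limit on both arrays. The remaining 2 genes differed in opposite directions, so a mixture cannot be told apart from a difference within the MCF-7 cells. Basal-like cells, and a response of the MCF-7 cells to G1P3 or to selection and passage, stay open as untested hypotheses.

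Ribosomal RNA and histone signals were higher in the G1P3 array. More labelled RNA without a poly(A) tail in that sample would raise other such RNAs as well, but the median log2 difference of 139 of them was -0.08, with 53 above 0 and the median at percentile 1.18 of random lists, which argues against it, although RN7SK was higher (148.4 and 323.1) and RN7SL1 was not (7109.3 and 6592.8). For the histone genes alone, more cells in S phase could account for the difference, since DNA replication and G1/S genes had a median of 0.10 with 29 of 43 above 0. That test is weak: the median fell inside the random range for an offset of 64 (0.08), and the G2/M list had a median of -0.01. An effect of G1P3 and a difference in growth state between the samples stay open.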

How the results depend on the processing

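The floor at the background limit was chosen after the data had been seen, and the other 10 alternatives were planned. No paired analysis was possible because each group had 1 array, and no replicate could be left out for the same reason. Most alternatives cannot turn the sign of a gene that keeps its probe, so the directions of the 30 named genes were hardly tested. Of their 323 values under the alternatives, 264 moved by less than the single-probe SD of 0.224, and HMCN1 was at 0 with the floor at the background limit. PPP2R2B was 0.34 under both floors, where a different probe represented it. Quantile normalization and median centring changed no call, but could move almost nothing in values already quantile-normalized. Of 47322 probes on each array, 14190 lay above the background limit, which is what signal over background leaves to measure. Except where a filter itself added or removed genes, the cause was not tested.

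Probe ILMN_2347798 of IFI6 had a log2 difference of 3.22 under both floors and 1.99 with an offset of 64. Genes at least 2-fold higher numbered 593 with the floor at the median signal and 28 with offset 64. Genes at least 2-fold lower numbered 33 with brightness from the 75th percentile, 30 with brightness on both arrays, 88 without the brightness limit, 86 with the floor at the background limit, 567 with the floor at the median and 13 with offset 64. Genes higher past 1.5-fold numbered 258 (75th percentile), 267 (both arrays), 852 (no limit), 1379 (floor at the median) and 103 (offset 64). Genes lower past 1.5-fold numbered 593 (40th percentile), 203 (75th percentile), 225 (both arrays), 765 (no limit), 1300 (floor at the median) and 64 (offset 64). The share of genes past 1.5-fold whose probes agreed in direction was 66.4% (40th percentile), 94.9% (75th percentile), 52.7% (no limit), 54.3% (floor at the background limit), 69.2% (floor at the median) and 92.4% (offset 64).

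Lists that moved inside the random range were the BCL2 family at 0.08 (75th percentile), 0.09 (both arrays), 0.04 (mean of probes) and 0.01 (floor at the background limit), G1/S at 0.07 (mean of probes) and 0.08 (offset 64), TGF-beta targets at 0.11 (40th percentile) and 0.06 (no limit), and interferon-stimulated genes at 0.09 (40th percentile) and 0.08 (no limit). Mitochondrial biogenesis did so at -0.07 (75th percentile, lowess and mean of probes) and -0.09 (floor at the median), and oxidative phosphorylation at -0.04 (40th percentile), -0.03 (mean of probes and offset 64) and -0.05 (no limit). The basal breast and HEK-type list did so at 0.20 (40th percentile), 0.17 (both arrays), 0.13 (mean of probes), 0.12 (no limit), 0.00 (floor at the background limit) and 0.11 (offset 64), and reversed to -0.02 at the 75th percentile. Ribosomal proteins at 0.10 (mean of probes) and glycolysis at -0.09 (75th percentile) moved outside it. Medians of the lists outside it under every alternative run ranged from 0.18 to 1.03 for basal and mesenchymal markers, 0.04 to 1.22 for fibroblast markers (lowest with the floor at the background limit, which ties the 5 of 10 genes below the limit at 0), 0.16 to 0.35 for histones and -0.20 to -0.10 for luminal markers, and 14 lists were inside it throughout.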

Other observations

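Of the tests in this part, those of gene order and of the genes around BCL2L1 were chosen after the result was seen. Other runs of neighbouring genes stood out less than those on chromosomes 15 and 20. The highest median of 15 neighbours was 0.45, from SURF2 to PIERCE1 on chromosome 9, above the 95th percentile of the highest medians in shuffled orders (0.42) but below their maximum (0.46). Over 11470 windows, 14 lay above that percentile and 26 below its counterpart for low medians (-0.405). The windows overlap, so these are not counts of separate runs. Windows from PRKCZ to LRRC47 (0.440) and from ECE1 to E2F2 (0.422) on chromosome 1 also passed the high percentile (0.418). So did the window from ATG4A to SLC6A14 (0.419) on chromosome X. Outside chromosomes 15 and 20 the lowest listed median was -0.349, from FOXD4 to PLGRKT on chromosome 9, which did not reach the low limit. Of the genes named in the lists, B2M lies in the stretch on chromosome 15 and UBE2C in that on chromosome 20. E2F2 ends one of the higher windows on chromosome 1. Restricted to genes above the background limit, 31 of 33 on chromosome 15 and 22 of 22 on chromosome 20 were lower, with medians of -0.44 and -0.41.

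A gained copy of the region around BCL2L1 was tested as a hypothesis for its higher signal. The 20 nearest genes of the brighter part were taken by gene order, whatever their distance from BCL2L1. They had a median log2 difference of -0.09, with 9 above 0, at percentile 9.43 of random sets. Just before BCL2L1, DEFB123 (0.55), HM13 (0.19) and ID1 (0.58) were higher. Genes just after it differed in both directions, with TPX2 at -0.21 and DUSP15 at 0.33. These values argue against a gain of the whole stretch from ACSS1 to COMMD7. They cannot decide on a gain of BCL2L1 alone, with a few of its neighbours, or of a part that leaves out the genes farthest from it.

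A general interferon response in the G1P3 sample was tested as a hypothesis for the higher interferon-stimulated genes. Of 13 core genes 6 were in the brighter part, with a median log2 difference of 0.17, 4 above 0 and percentile 84.3 (central 95% of random lists, -0.31 to 0.32). ISG15 had signals of 407 and 563.4 and IRF9 of 114.6 and 84.8, while IFI44, IFI44L and OAS1 of the 6, and IFIT1 (6.3 and 4.6) and MX1 (0.3 and -2.2) outside them, were below the background limit on both arrays. With so few measured core genes the hypothesis stays open.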
